A study of Drosophila melanogaster with 2 samples.

How the data were processed

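The data are ChIP-seq peak lists from whole Drosophila melanogaster embryos, 0 to 8 h old, that expressed Dan fused to eGFP, with 2 biological replicates per the labels. Chromatin was sheared by sonication to 200 to 800 bp and precipitated with an antibody against GFP, per the labels. The lists are on the dm6 build, per the labels, and were made from filtered alignments of the replicates and of a control, per the sample notes. The aligner, the peak caller and their versions are not given in the sources used here, and neither is the depth of each library.

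Each list holds regions with a signal, a scaled score and a −log10 q. The signal is the authors' peak caller's own value per region against a control. Its scale is not stated, so it was used to rank and describe peaks within a list and was compared between the replicates only by rank or correlation. All 1170 conservative peaks have the same place and signal in the ranked list used, so signals of these 2 lists were set side by side. The deposited score is a scaled logarithm of the IDR, with a maximum of 1000. The deposited −log10 q column was used only as an alternative to the signal, and the column for p held -1 throughout. The IDR measures how well the rank of a region agrees between 2 sets of calls. Regions are at most 350 bp wide in the lists made from both replicates.

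The authors deposited, for each replicate, a list of ranked regions and a list past a threshold, and for both replicates together 2 ranked lists and 2 thresholded lists. The lowest score in the thresholded lists was 830 or 831, which is an IDR of 0.01. The design written before the data were examined had assumed 0.05, so its stricter setting of 0.01 removed no peak. Thresholds of 0.001 and 0.05 were added after the data were seen. All 1170 conservative peaks were found at or under the threshold in 1 of the ranked lists, whose intervals were identical to regions of replicate 1 in 78.4% and of replicate 2 in 80.8%. In the other ranked list 123 of them were missing or over the threshold, and its intervals matched the replicates' own regions in 0.00153% and 0.000766%, so it was not used further. Of the regions at or under the threshold in the ranked list used, 160 were not in the conservative list. A further file of unstated content entered the thresholded lists, per the sample notes.

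The reference was Ensembl release 115 (BDGP6.54) with the matching RefSeq sequence, which is the Release 6 assembly that dm6 is built from. Gene comparisons used the 7 arms 2L, 2R, 3L, 3R, 4, X and Y, with 13968 protein-coding genes. All 514 written list symbols were matched, 6 of them through older names.

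Control regions were the 125044 ranked regions on the arms with an IDR above the threshold that overlapped no thresholded peak. Their median signal was 20.2. They share the libraries, the mappability and the processing of the peaks but are weak regions, not unbound sequence. For the location classes, 20 controls per peak were drawn on the same arm and compared by two-sided Fisher's exact tests with Benjamini-Hochberg adjustment over the classes. Each summit was assigned to the protein-coding gene with the nearest TSS, and ties were settled by position and then identifier order. For each of 26 gene lists the number of occupied members was compared with 10000 draws of controls matched on arm and on distance to the TSS, with a two-sided permutation p adjusted over the lists. The background was the protein-coding genes nearest to at least 1 ranked region. The ranked regions include the peaks, so every occupied member was kept, while members nearest to no ranked region were left out. A gene whose only ranked region is a peak could not be drawn from the controls, which can lower the expected count. For 27 consensus strings and all 6-mers, windows of 100 bp either side of the summit were compared with up to 5 controls per peak matched on arm, GC content in steps of 5% and TSS distance. Strands were combined. Overlaps between replicates needed at least 1 bp and were compared with 1000 random placements. Correlations used 100000 resamples. Intervals of shares are exact binomial intervals at 95% and cover counting error only, and the limit for a count of 0 is 3 counts of the total.

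The named genes were fixed by rule before the data were examined. They are dan, danr and w, with the marker genes y and v for the test of loci, the genes nearest to the 25 strongest conservative peaks on the arms that overlap a peak of both replicates' lists, and up to 4 occupied members per list with the highest signal. The genes sharing a peak with them, CG32795 and lobo, the mitochondrial ribosomal protein gene mRpL41, the genes with the most peaks and members of a list beyond the strongest 4 were named after their values were seen.

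Scripts used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. The functions were tested on simulated data. In 20 sets of 1000 peaks drawn from controls, 0 sets had a gene list past the adjusted threshold. The background of the simulated sets came from controls alone, so they did not test a background that includes the peaks. With a peak planted at 50% of the members of a list, or at least 4, the list was recovered in 9 of 20 sets, and with a peak at every member in 20 of 20. Of 10 6-mers planted in 10% of windows each, 10 were recovered, and 0 of 2080 passed with none planted. Since planted lists were missed at 50%, a list that did not pass may still hold occupied genes beyond chance.

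Alternatives were the other thresholded list, each replicate's own list, other IDR thresholds, other overlap rules, other TSS distances, other ways to assign genes, other windows and other controls. The 6-mers were tested under the same alternatives as the consensus strings. Alternatives added after the data were seen were the IDR thresholds of 0.001 and 0.05, the removal of peaks below the median signal of the ranked list (20.3), controls also matched on GC content or matched on it in each part or over 250 bp windows and, for the dan locus, each replicate's own list and overlapping peaks counted once. On the arms, 74 peaks overlapped another conservative peak, and these included 27 of the 28 peaks with a signal below that median.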

Results

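Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was used to map where the nuclear protein Dan sits on the genome of the Drosophila melanogaster embryo. Dan is the product of distal antenna (dan), a gene known for its part in antennal identity and, with its neighbour distal antenna-related (danr), in eye and neuroblast development. The flies carried dan fused to eGFP, a green fluorescent protein, and the tagged protein was precipitated with an antibody against GFP. Whole embryos aged 0 to 8 h formed a single group of 2 biological replicates, and no second condition was compared. The comparisons the design allows are therefore those between the replicates, between peaks and weaker regions of the same libraries, and between groups of genes. The depth of each library is unknown, since the lists give a signal per region and no read counts.

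Replicate 1 had 1071 peaks past the authors' threshold on the irreproducible discovery rate (IDR), and replicate 2 had 600. The conservative list, which compares the replicates with each other, held 1170 peaks with a median signal of 104. Of these, 1078 lay on the chromosome arms, where they numbered 205 on 2L, 197 on 2R, 221 on 3L, 246 on 3R, 202 on X and 7 on Y. Their density was close to even over the long arms, from 7.67 peaks per Mb on 3R to 8.72 on 2L. Chromosome 4 held 0 peaks, against 10.8 expected from its length, and 39 ranked regions in all. The remaining 92 peaks lay on unlocalized X scaffolds and were left out of the comparisons with genes.

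The question of whether the replicates marked the same places was answered first from each replicate's own list. Of the 600 peaks of replicate 2, 491 overlapped a peak of replicate 1, or 81.8% (95% exact interval 78.5 to 84.8%). On the chromosome arms the share was 83.8%, against a mean of 0.422% when the peaks were placed at random on the same arms (one-sided permutation p = 0.001, the smallest 1000 placements can give). Draws from replicate 2's regions that missed the threshold overlapped replicate 1's peaks in 0.397% on average. In the other direction, 46.6% of replicate 1's 1071 peaks (43.6 to 49.6%) overlapped the list of replicate 2.

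Most peaks of replicate 1 outside the list of replicate 2 still overlapped a ranked region there. Of these 572 peaks, 422 overlapped a ranked region of replicate 2 and the others none. That ranked list holds 111665 regions with a summed width of 33.5 Mb. Some overlaps would arise at random, and their share was not computed. The 422 stood at a median of the 98th percentile of all ranked regions of replicate 2 by signal (quartiles 91.9 and 99.1). The 109 peaks of replicate 2 outside the list of replicate 1 included 92 with a ranked region in replicate 1, at a median percentile of 96.7. Across the 1150 conservative peaks with a signal in both replicates, Spearman's rho of the signals was 0.68 and Pearson's r on the log10 scale 0.82 (permutation p = 1e-05 for both, the smallest 100000 resamples can give). Peaks are not independent replicates, and the list was chosen by rank agreement, so these values describe the listed peaks alone. With the 50% of peaks with the highest mean signal left out, rho was -0.18, but that choice selects on the mean of the same 2 values and by itself lowers their correlation.

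**Figure D1:**
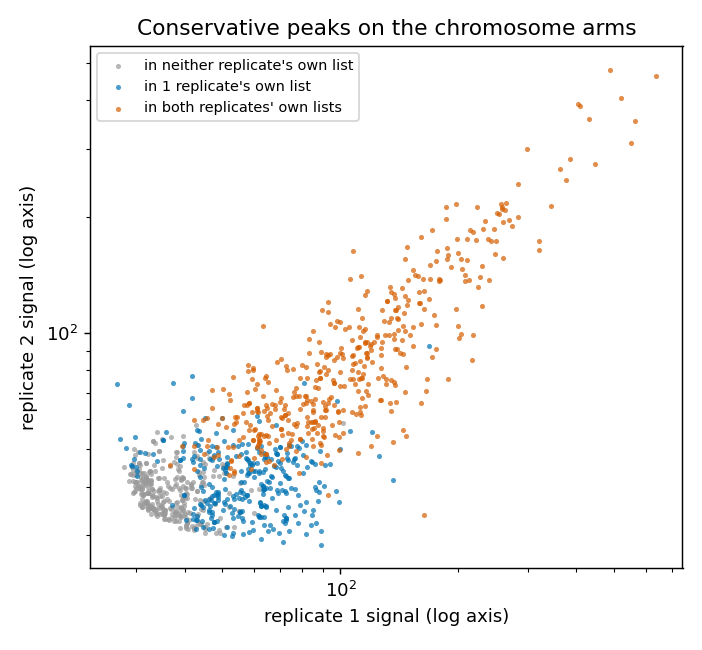
Signal of replicate 1 (horizontal, log axis) and replicate 2 (vertical, log axis) at conservative peaks on the chromosome arms, 1 point per peak, coloured by whether the peak is also in each replicate's own list. The 450 peaks in both lists extend to the strongest signals, and the 315 in neither sit in the weakest corner.

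The strongest peaks found in both replicates lay beside Adf1, ph-p, px, CG14100 and CG7601. The highest signal, 1079, was in an intron of Adf1, which encodes a sequence-specific transcription factor, at 6662904 to 6663207 on 2R (dm6), 800 bp from the nearest start site (TSS). Its signal was 637 in replicate 1 and 463 in replicate 2. Next was ph-p (polyhomeotic proximal, a Polycomb group protein), with a signal of 951 at 2137200 to 2137498 on X, 498 bp from its TSS and within an intron. The peak in an intron of px, at 22514170 to 22514448 on 2R, reached 914. Chro, which encodes the chromosomal protein Chromator, had 787 at 22878750 to 22879017 on 3L, in an exon 107 bp from its TSS. Sox14, an HMG-box transcription factor gene, had 589 between genes, 233 bp from its TSS at 23978431 to 23978671 on 2R.

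Many of these summits fell close to 100 bp from a start site, several of them between genes that face away from each other. CG7601 and CIA30 shared a peak of signal 844 at 29736709 to 29736983 on 3R, with its summit 103 bp and 117 bp from their start sites. Tcs5 and CHMP2B shared one of 764, at 101 bp and 123 bp. The mitochondrial ribosomal protein gene mRpS10 and Art3 shared one of 717, at 127 bp and 130 bp, and the tubulin acetyltransferase gene Atat and Shc shared one of 664, at 123 bp and 129 bp. Ugalt, a UDP-galactose transporter gene, had a peak of 789 at 47 bp, and CG14100 one of 908 at 91 bp. Signals from 462 to 627 were found beside CG13921, CenG1A, CG1888, tara, CG11050, CG31668, CycB, CG5611, RasGAP1, LPCAT, HmgZ, PNPase, CG32772 and mRpL23. Of these 25 peaks, 16 lay within 500 bp of a TSS. All 25 were named by a rule that required presence in both replicates' lists, so their agreement between replicates is not an independent result.

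Peaks were concentrated at promoters. Of the 1078 summits on the arms, 413 lay within 500 bp of an annotated TSS, or 38.3% (95% exact interval 35.4 to 41.3%), against 9.80% of 21560 weaker control regions of the same arms (odds ratio 5.72, adjusted p = 1.5e-126, two-sided Fisher's exact test). Within 200 bp the shares were 26.3% and 4.09%. The share within 500 bp was 53.8% at IDR of at most 0.001 (odds ratio 10.9) and 23.8% at 0.05 (odds ratio 2.90). Exons outside promoters held fewer peaks, 7.33% against 26.0% (odds ratio 0.225, adjusted p = 2.1e-53, Fisher's exact test). Introns outside promoters held 31.4% against 38.5% (odds ratio 0.733, adjusted p = 3.5e-06), and the remaining intergenic sequence 22.9% against 25.7% (odds ratio 0.858, adjusted p = 0.0381, Fisher's exact tests). The classes share 1 total, so the excess at promoters by itself lowers the other shares. These tests therefore do not show that peaks avoid introns or intergenic sequence. The controls were matched on arm only. Mean GC content within 100 bp of the summit was 39.4% at peaks and 47.6% in controls, and its part in the lower share of exons was not tested. Outside promoters, exons, introns and intergenic sequence held 79, 339 and 247 peaks, against 5599, 8301 and 5547 controls.

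The strongest peaks were the most promoter-bound and rich in A and T. From the strongest to the weakest signal quintile, the share within 500 bp of a TSS was 57.9%, 44.4%, 35.3%, 32.4% and 21.4%. The mean GC content within 100 bp of the summit was 35.5% (SD 6.53 across 216 peaks) in the strongest quintile and 47.6% (SD 10.4 across 215 peaks) in the weakest, where control regions had 47.6% and random positions 42.1%. The share also in replicate 2's own list was 99.5% in the strongest quintile and 6.98% in the weakest. With control regions matched on GC content, the promoter share of controls was 10.8%.

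**Figure D2:**
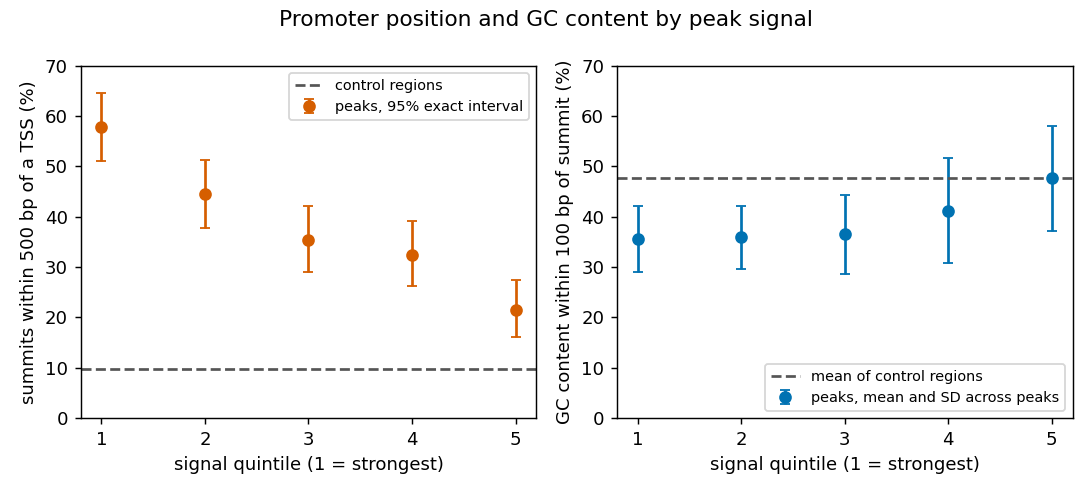
Left, the share of summits within 500 bp of a TSS by signal quintile, with 95% exact intervals, and the control regions as a dashed line. Right, the mean GC content within 100 bp of the summit with the SD across peaks, and the mean of control regions as a dashed line. The promoter share is 57.9% in the strongest quintile and 21.4% in the weakest, and the GC content is 35.5% and 47.6%.

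Summits within 200 bp of annotated ncRNA genes made up 7.14% against 4.20% of controls (odds ratio 1.76, adjusted p = 8.0e-05, Fisher's exact test). These controls were matched on arm and not on TSS distance, and 38.3% of peaks but 9.80% of controls lay within 500 bp of a TSS. The excess at ncRNA genes was therefore not separated from that at promoters. None of the 1078 summits lay within 200 bp of an annotated tRNA, snoRNA or snRNA gene, which allows a share of up to 0.278%. Control regions had 0.0278%, 0.0325% and 0.00464%, so a preference for these genes is not excluded. Annotated transposable elements held 1.30% of summits and 1.32% of controls (adjusted p = 1, Fisher's exact test).

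The fixed gene lists asked which groups of embryonic genes lay nearest to peaks. The 1078 peaks were nearest to 865 protein-coding genes, of 10923 nearest to any ranked region. Of 26 lists, 3 held more such genes than 10000 matched draws of control regions gave, with an adjusted permutation p under the threshold of 0.05, and none held fewer. The unadjusted p was under 0.05 for 5 lists. A member counts as occupied when its TSS is the nearest, which says nothing on whether its expression depends on Dan. Counts are out of the members in the background, which leaves out listed genes nearest to no ranked region.

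Of 17 listed cell cycle genes, 10 were in the background. Of these, 4 were occupied, against 0.243 expected (permutation p = 0.0002, the smallest the draws can give, and adjusted p = 0.0052). They were CycB, the mitotic cyclin B, with a signal of 481 at 3348 bp, and the transcription factor gene Dp with 88.5 at 257 bp. The others were trbl, a mitotic inhibitor, with 86.3 at 1426 bp, and dap, a cyclin-dependent kinase inhibitor, with 63.7 at 7257 bp. This was the stronger of 2 peaks assigned to dap and was in neither replicate's own list. The peak at trbl was only in replicate 1's. The adjusted p missed the threshold in 6 of 12 alternative settings, among them replicate 2's list alone, with 2 genes against 0.111 expected, and the other thresholded list of the series, with 2 against 0.301. The ratio of observed to expected was 16.4 in the main setting, 18 with replicate 2's list and 6.65 with the other list. Over the alternatives it ran from 4.04 with every gene with a TSS within 5000 bp to 20.1 with controls also matched on GC content. With random positions as controls it was 5.46, and the expected count was 0.733.

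Of 11 listed genes of the epidermal growth factor (EGF) receptor pathway, 10 were in the background. Of these, 6 were occupied, against 1.62 expected (permutation p = 0.0020, adjusted p = 0.0260). The strongest peaks were at aop, an ETS repressor gene with 5 peaks and a highest signal of 345, S (Star) with 274, aos (argos, a secreted inhibitor) with 255 and ru (roughoid) with 161. Each replicate's own list gave an adjusted p under the threshold, with 6 genes against 1.51 expected for replicate 1 and 5 against 0.720 for replicate 2. The adjusted p missed it in 5 of 12 alternative settings, among them every gene with a TSS within 5000 bp and random positions as controls. The ratio of observed to expected was 3.70 in the main setting, and 5.87 and 2.82 in these. At IDR of at most 0.05, where the adjusted p also missed it, the ratio fell to 1.58, with 6 genes against 3.79 expected.

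Of 13 listed heat shock genes, 8 were in the background. Of these, 3 were occupied, against 0.306 expected (permutation p = 0.0044, adjusted p = 0.0381). Hsp27 had a signal of 289 at 156 bp from its TSS, Hsp83 had 142 at 1071 bp and Hsc70-4 had 88.9 at 186 bp, in neither replicate's own list. The adjusted p missed the threshold in 6 of 12 alternative settings, among them each replicate's own list. The ratio of observed to expected was 9.79 in the main setting, 6.79 with replicate 1's list and 12.4 with replicate 2's, with 2 genes occupied in each.

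Among the lists that did not pass, Polycomb and Trithorax group genes had 3 of 14 occupied, ph-p, E(z) with a signal of 161 and ph-d with 142, against 0.609 expected (permutation p = 0.0402, adjusted p = 0.209). With replicate 1's own list, the other thresholded list or IDR of at most 0.001, this list passed. Glial and hemocyte genes had 5 of 12 occupied, led by ush, crq, pnt and Pxn, above the 95% range of the draws of 0 to 4 (permutation p = 0.0210, adjusted p = 0.136). Dorsal ectoderm and amnioserosa genes had 6 of 19, led by tup with 185, ush with 129, Doc2 with 128 and brk with 114 (adjusted permutation p = 0.249).

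The lists closest to the known roles of dan did not pass the threshold. None of the 8 retinal determination genes in the background was occupied, against 1.31 expected. Antenna and distal limb genes had 5 of 16 occupied, bab2 with a signal of 138, Antp with 128, Lim1 with 121, bab1 with 91.0 and al, against 3.58 expected (adjusted permutation p = 0.990 for both lists). With replicate 1's own list, antenna and distal limb genes had 7 occupied against 3.19 expected, above the 95% range of the draws of 1 to 6 (adjusted permutation p = 0.176). At IDR of at most 0.001 they had 0, against 0.845 expected. Of the neuroblast temporal series, 1 of 6 was occupied, grh with 199, against 0.668 expected, and of the neuroblast stem cell genes 2 of 12, baz with 293 and insc with 182, against 1.24 (adjusted permutation p = 1 for both). The summit at insc was as far from the TSS of sktl, 2053 bp, and was assigned by the rule for ties. Proneural and neuroectoderm genes had 2 of 10, Dr with 115 and D with 76.7.

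Segmentation genes gave no list past the threshold. Pair-rule genes had 3 of 9 occupied, slp2 with a signal of 249, odd with 133 and ftz with 120 (adjusted permutation p = 0.492). Segment polarity genes had 3 of 12, mid with 215, nkd with 129 and ptc with 112, gap and head gap genes 2 of 10, oc with 147 and ems with 146, and Hox genes 1 of 8, Antp. Their adjusted permutation p was 0.770, 1 and 1.

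The other tissue lists, and those of the ecdysone cascade, housekeeping and ribosomal protein genes, had counts within the 95% range of the draws. Mesoderm and muscle genes had 3 of 14 occupied, zfh1 with a signal of 283, kirre with 210 and stumps with 137. Endoderm and gut genes had 2 of 7, bowl with 234 and drm with 84.0. Trachea, salivary gland and epidermis genes had 3 of 9, grh, trh with 84.6 and vvl with 80.3. Neuronal differentiation genes had 1 of 13, elav with 265, 252 bp from its TSS. Ecdysone cascade genes had 4 of 10, Hr3 with 313, Hr4 with 191, Eip75B with 133 and usp with 79.5, against 3.30 expected. The summit at Hr3 was as far from the TSS of CG46321, 7864 bp, and was assigned by the rule for ties. Housekeeping genes had 1 of 6, Act5C with 179. Cytoplasmic ribosomal protein genes had 4 of 55, RpL34b with 145, RpS10a with 75, RpL38 with 72.6 and RpS28b with 62.9. None of the Notch pathway, germline, early zygotic or histone genes in the background was occupied, and these lists had 7, 9, 10 and 3 members there.

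**Figure D3:**
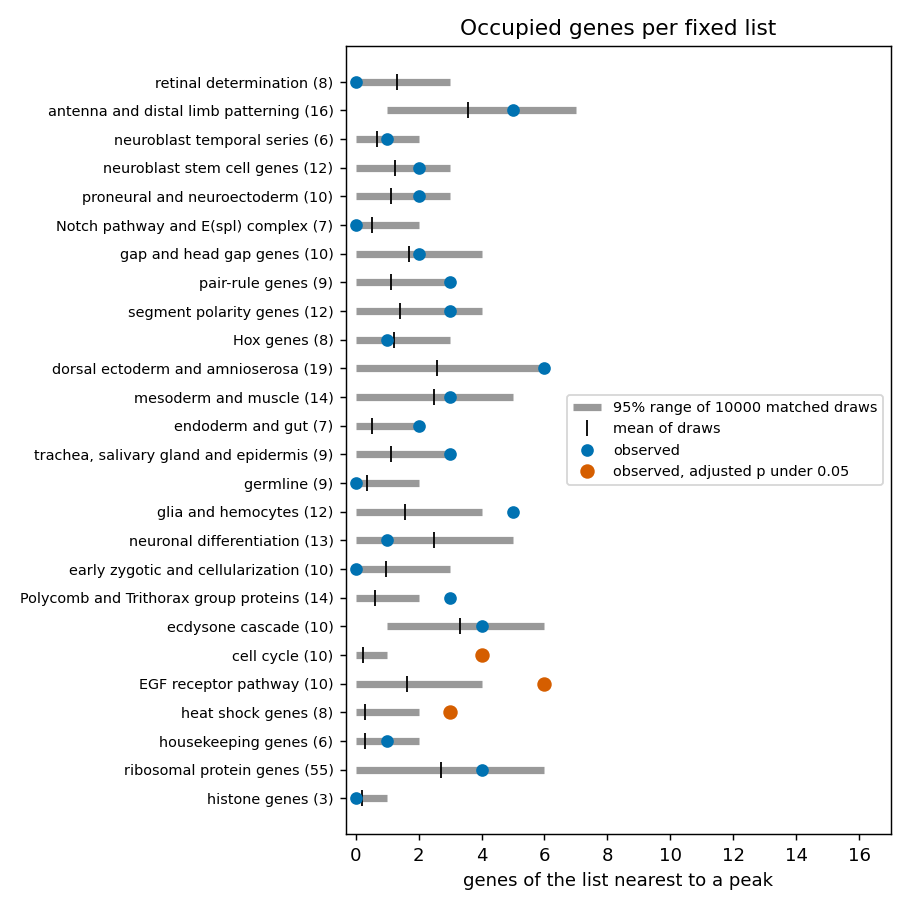
Number of genes per fixed list whose TSS is nearest to a conservative peak (circles), with the mean (tick) and 95% range (grey bar) of 10000 matched draws of control regions. The number of members in the background is in brackets. Cell cycle, EGF receptor pathway and heat shock genes, in orange, have an adjusted permutation p under 0.05.

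None of the 27 fixed motifs passed the test between peaks and matched controls in the main setting. Some 6-mers did, among them several sharing the core CAGTG and GAGAGA, a part of the GAGA repeat. Of 27 fixed motifs, 0 differed between the 201 bp windows of 1078 peaks and 4934 controls matched on arm, GC content and TSS distance after adjustment (Fisher's exact test), and 6 had an unadjusted p under 0.05. The Zelda site CAGGTAG was in 1.30% of peaks and 0.912% of controls, the GAGA repeat in 3.25% and 2.11% (adjusted p = 0.177), and the Hunchback string TTTTTTG in 12.6% and 16.2% (adjusted p = 0.0924, Fisher's exact tests). The shorter GAGAGA was in 11.3% and 6.34% (odds ratio 1.88, adjusted p = 6.8e-06 over all 6-mers, Fisher's exact test). In windows of the same width, 3 motifs passed with the other thresholded list, all less frequent at peaks. With controls matched on GC content only, 6 passed, 2 more and 4 less frequent, and with windows 1000 bp away 1 passed, less frequent. In windows of 250 bp either side, 12 motifs passed, 5 of them more frequent at peaks and 7 less frequent. The more frequent included the GAGA repeat with 13.7% against 5.92% (odds ratio 2.53, adjusted p = 5.0e-15) and the M1BP site with 3.34% against 1.01% (odds ratio 3.37, adjusted p = 2.7e-06, Fisher's exact tests). The less frequent included the homeodomain site TAATTA with 23.5% against 29.5% (odds ratio 0.732, adjusted p = 0.00051) and the POU octamer with 6.12% against 9.57% (odds ratio 0.617, adjusted p = 0.0017, Fisher's exact tests). These controls were matched on GC content within 100 bp only. With GC content matched over the 250 bp windows, added after the data were seen, 10 motifs passed, 5 in each direction, with TAATTA at 27.0% of controls (adjusted p = 0.0460) and the POU octamer at 8.98% (adjusted p = 0.0121, Fisher's exact tests).

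Among all 2080 6-mers, 120 were more frequent at peaks and 69 less frequent at an adjusted p under 0.05. The 5 with the smallest p all held CAGTG or its reverse complement. ACAGTG was in 19.8% of peaks and 8.98% of controls (odds ratio 2.5, adjusted p = 1.7e-18, Fisher's exact test), CAGTGC in 20.6% and 10.8%, CACTGA in 18.5% and 9.75%, ACACTG in 18.0% and 9.63%, and CAGTGG in 18.0% and 9.77%. ACAGTG was in 22.3% of replicate 2's own peaks (adjusted p = 9.3e-14) and 24.6% of replicate 1's (adjusted p = 1.5e-34, Fisher's exact tests). The core itself was in 54% of peak windows (95% exact interval 51 to 57%) and 32.9% of controls (odds ratio 2.40, Fisher p = 1.3e-37). This core was chosen after its values were seen. With windows 1000 bp from the same summits as controls, which are not matched on GC content, 252 6-mers were more frequent and 285 less frequent. AAATAT then had the smallest p, with 46.3% against 25.7% (adjusted p = 7.0e-28, against 3.8e-17 for ACAGTG, Fisher's exact tests). With windows of 50 bp either side, 112 were more frequent, and these included 0 of the 8 6-mers holding the core. The core was in 46.7% of peaks within 500 bp of a TSS and 58.5% of peaks farther away, against 32.2% and 32.5% of their controls.

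The core lay mainly beside the summits. From 50 to 150 bp before the summit 40.4% of peaks held it, against 19.2% of controls (odds ratio 2.86, Fisher p = 2.8e-46), and from 50 to 150 bp after it 39.9% against 19.1% (odds ratio 2.81, Fisher p = 1.1e-44). Within 50 bp of the summit the shares were 20.9% and 18.4% (Fisher p = 0.0711). The orientation of the 6-mer differed between the sides. On the plus strand, ACAGTG was in 132 peaks on the side before the summit and 42 on the side after it, while its reverse complement CACTGT was in 38 and 132 (odds ratio 10.9, Fisher p = 4.1e-24). The same peak can enter several of these counts, which the test treats as independent, so its p does not hold as given. Mean GC content in 20 bp steps was 35.5% just after the summit and 46.1% from 120 to 140 bp after it, against 40.7% and 42.2% in the controls, which were matched over 201 bp as a whole. With controls matched on the GC content of each part, an alternative added after the data were seen, their shares were 19.5% before, 16.5% within 50 bp and 19.7% after (odds ratios 2.80, 1.33 and 2.71, Fisher p = 2.2e-45, 0.00082 and 1.8e-42).

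**Figure D4:**
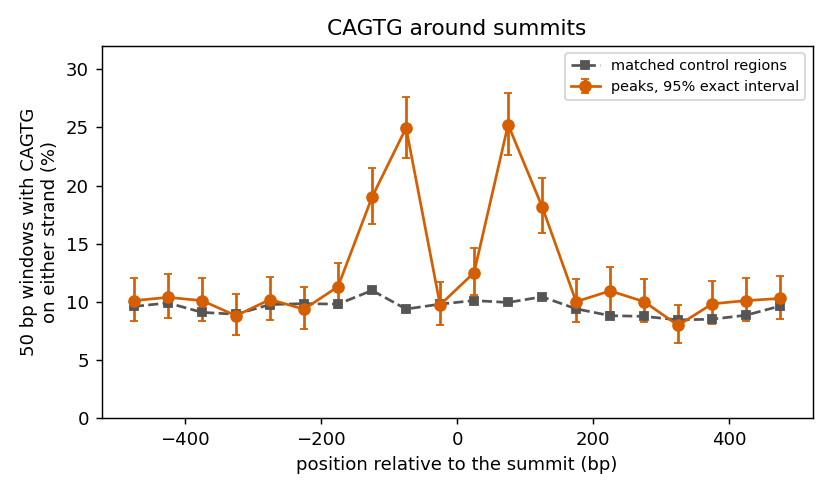
Share of 50 bp windows holding CAGTG on either strand (vertical) by position relative to the summit (horizontal), for 1078 peaks with 95% exact intervals and for 4934 matched control regions. Peaks reach 25% and 25.2% in the windows from 50 to 100 bp on either side and 9.74% and 12.5% in the windows just before and just after the summit, while controls stay between 8.45% and 11.0%.

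The tagged gene's own locus was examined separately, and the labels do not name the construct that carries the tag. Within 5000 bp of dan (25184383 to 25192806 on 3R, plus strand) lay 3 conservative peaks, as many as in 0.706% of 1558 genes of similar length, whose mean was 0.215. Of these, the peak at 25188873 to 25189222, with a signal of 75.1, was inside the gene and in replicate 1's own list. The others, with 81.6 and 6.96, overlapped each other at 25193119 to 25193667 in an exon of the overlapping gene lobo and were in neither replicate's list. Counted once, they leave 2, as many as in 2.57% of these genes when overlapping peaks are counted once throughout. The strongest peak of the neighbourhood, with 269, lay 5675 bp from the TSS of dan at 25178533 to 25178882 and was in both lists. Within 20000 bp there were 5 peaks.

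The related gene danr (25138072 to 25139903 on 3R) had 0 peaks within 20000 bp, as did 65.6% of 4563 genes of similar length, and 0 ranked regions within 5000 bp. Between 25067307 and 25146531 on 3R, a stretch that holds danr, there was no ranked region, so no peak could be called. The 21 ranked regions within 20000 bp of danr all lay at or beyond its upper end, so the count of 0 says nothing on binding at danr itself. The marker genes y and v on X also had 0 peaks within 20000 bp, as did 62.6% and 65.7% of genes of similar length. No ranked region lay within 20000 bp of y, so no peak could be called there. The marker gene w (2790599 to 2796466 on X) had 0 peaks inside it and 1 within 5000 bp, at 2786637 to 2786986 in an intron of CG32795, with a signal of 101 and in replicate 1's list alone. Of 2104 genes of similar length, 16.3% had at least 1.

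**Figure D5:**
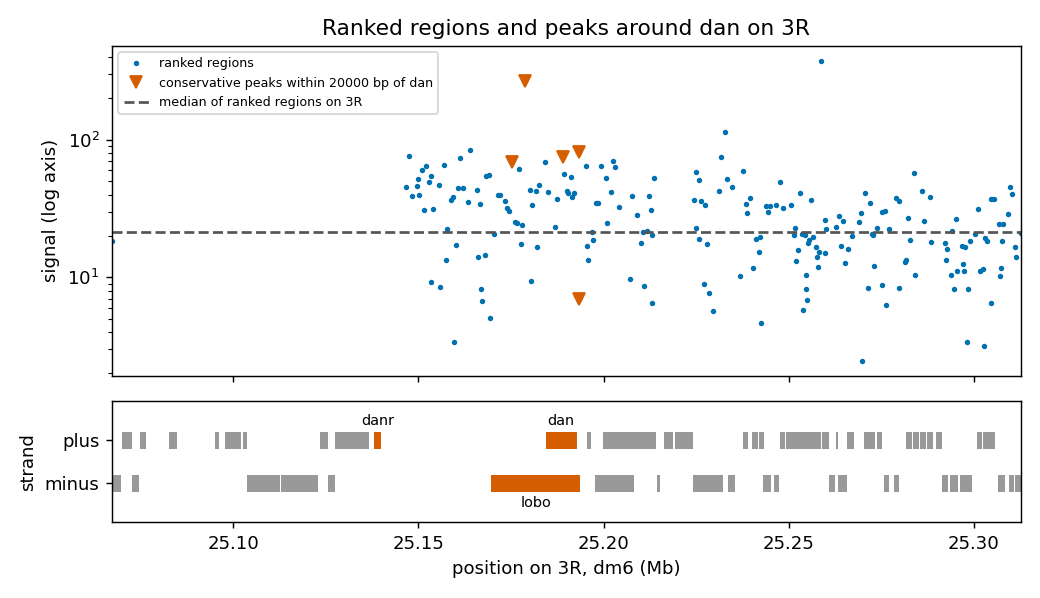
Signal of ranked regions (dots, log axis) and of conservative peaks within 20000 bp of dan (triangles) along 3R, above the protein-coding genes of each strand. The dashed line is the median signal of ranked regions on 3R, 21.3. Regions around dan lie mostly above that line, and the stretch holding danr has no ranked region.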

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

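The tests of ACAGTG 1000 bp from summits and of GC content beside them were chosen after the result was seen; the other tests here were written before their results. No biological explanation was tested, since the design has a single group. Signal in data outside the comparisons was present in 92 conservative peaks on 52 unlocalized X scaffolds, with a median signal of 103 and a highest of 688. It was also present in 160 ranked regions at or under the authors' IDR threshold that the conservative list leaves out. Of these, 88 lay on unplaced or unlocalized scaffolds and 47 on X beyond position 22000000, and the highest signal was 3063.1 in all and 989 on the arms, against 1079 at the strongest listed peak on the arms.

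The raised density of peaks at dan may come from extra copies of the locus in the tagged strain. With peaks left out, the 58 ranked regions within 20000 bp of dan had a median signal of 33.8, at the 99.9th percentile of 13423 genes with at least 5 such regions, whose median was 20.4. Extra copies would raise all regions alike if the control lacked them. The strain of the control is not given in the sources used here, so the values cannot decide this explanation. In 10000 bp steps the median ran from 32 to 46.0 between 25140001 and 25210000 on 3R, against 21.3 over the arm. Step medians above that stretch fell to 21.3 and 22.6 before a further value of 43.9. Below it, no ranked region lay between 25067307 and 25146531, and the cause was not tested. The peak of signal 269 in both lists stands above the regions around it, and whether Dan binds there in flies without the tag stays open.

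Chromosome 4 had 39 ranked regions and 0 peaks, and neither its low GC content nor its repeats accounted for this. The density of ranked regions on the other long arms rose with GC content, from 3.23 per 100 windows of 350 bp below 30% GC to 61.3 above 55%. From that relation the GC profile of chromosome 4 predicted 693 regions, 17.8 times the number observed (95% interval 13 to 25). In windows free of masked repeats its density was 7.38% of that of the other arms (95% interval 3.68 to 13.2%). A difference between the chromatin and its control on this chromosome, or a filter in the authors' processing, could each leave such a gap and was not tested.

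The core CAGTG beside summits was accounted for neither by the wider region, since ACAGTG was 2.35 times as frequent at summits as 1000 bp away (95% interval 1.97 to 2.84), nor by the GC content beside summits, since with that content matched the odds ratios were 2.80 and 2.71 (95% interval 2.36 to 3.11 for the smaller). The low GC content at the summit was not excluded as a source of the dip there. The core's share 50 to 150 bp away was 1.92 times its share within 50 bp (95% interval 1.68 to 2.20), above each of the 79 other 5-mers of the same composition, whose median was 1.32 and highest 1.73. The core was chosen from windows of the same peaks after its values were seen, so its rank may be partly set by that choice. A single oriented site with a displaced summit could not be told apart from paired sites. The core was on both sides in 220 peaks against 179 expected, a ratio of 1.23 (permutation p = 0.0001, the smallest 10000 draws can give), between the values set for each.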

How the results depend on the processing

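The overlap of the replicates, the promoter share and the direction of every gene list that passed kept their direction under all alternatives run for them. The promoter share ranged from 23.8% at IDR of at most 0.05 to 53.8% at 0.001. The count of peaks was 361 at IDR of at most 0.001 and 2712 at 0.05 (both added after the data were seen), and 600 to 1071 with single replicates. The correlation of the replicates' signals changed sign, to a rho of -0.18, when the 50% of peaks with the highest mean signal were left out. That choice selects on the mean of the same 2 values, which by itself lowers their correlation.

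The number of gene lists past the threshold was 3. It was 0 at IDR of at most 0.05 (2 lists with an unadjusted p under 0.05), 0 with every gene within 5000 bp counted (3 lists) and 0 with random positions as controls (4 lists), and 1 to 3 with single replicates. The 3 lists together missed the adjusted threshold in 17 of 36 alternative settings, always with more genes occupied than drawn, and the cause was not tested. The number of motifs past the threshold was 0 in the main setting, 3 with the other thresholded list, 2 with 50 bp windows, 12 with 250 bp windows, 10 with GC content matched over those windows, 6 with controls matched on GC content only and 1 with windows 1000 bp away. The number of 6-mers more frequent at peaks was 120 in the main setting, 48 at IDR of at most 0.001, 181 with 250 bp windows, 202 with GC content matched over those windows, 252 with windows 1000 bp away and 71 to 134 with single replicates. The cause of these changes was not tested.

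At dan the count of 3 peaks became 5 within 20000 bp and 1 inside the gene body, was 2 with overlapping peaks counted once, and was 0 to 1 with single replicates. The IDR setting of 0.01 removed no peak, so it is counted among the alternatives but tests nothing. The overlap and the correlation need both replicates, so no value without one exists. No paired analysis was possible because there is a single group. Depth per library is unknown, so the shorter list of replicate 2 cannot be set against its reads.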

Other observations

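The tests of signal against TSS distance and of mitochondrial ribosomal protein genes were chosen after the result was seen, and that of divergent genes before. Peaks at promoters lay upstream of genes and between divergent gene pairs. Of 413 summits within 500 bp of a TSS, 85.5% were upstream of the nearest TSS, against 41.4% of 2065 control regions matched on arm and distance (odds ratio 8.34, Fisher p = 8.9e-65). Between start sites of a divergent pair, each within 500 bp, lay 169 of them, or 40.9%, against 4.46% of controls (odds ratio 14.9, 95% interval 11.2 to 19.8, Fisher p = 1.9e-79). Among upstream summits alone the shares were 42.2% and 9.72% (odds ratio 6.78, Fisher p = 1.2e-35). The controls of these comparisons were not matched on GC content. Its mean was 39.4% over all peaks on the arms and 47.6% in control regions of the same arms, and its part in these differences was not tested. Pairs named above include CG7601 and CIA30, Tcs5 and CHMP2B, mRpS10 and Art3, and Atat and Shc. The median signal was 130 at divergent pairs and 123 at the other promoter peaks, a difference that was not tested. A hypothesis is that Dan or its partners may prefer promoters shared by divergent genes. These data do not separate this from a preference for open promoter chromatin, since no accessibility data were used here.

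Stronger peaks lay closer to a TSS, with Spearman's rho of -0.30 between signal and distance across 1078 peaks (permutation p = 1e-05, the smallest the resamples can give). Peaks are not independent replicates. Mitochondrial ribosomal protein genes, noticed because mRpS10 and mRpL23 carry peaks with signals of 717 and 462, had 3 of 45 members occupied, mRpL41 among them with 416. The draws gave 1.77 (95% range 0 to 5, permutation p = 0.520). The test counts occupied members and does not cover their signal, so whether the group stands out stays open.

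Several genes had many peaks assigned by nearest TSS, which need not lie inside the gene. Pzl had 7, and DIP-lambda, Myo81F, DIP1 and hng3 had 6 each. Pzl, DIP-lambda and Myo81F span 709421 bp, 379081 bp and 1965857 bp, while DIP1 spans 5353 bp and hng3 17810 bp. These lengths do not give the density of peaks within a gene. The temporal patterning gene chinmo, the ecdysone-responsive gene Hr4 and dan itself had 4 each.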
